A study of Mus musculus with 18 samples.

How the data were processed

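Transcript levels were measured by sequencing of total RNA from skeletal muscle, white adipose tissue and brown adipose tissue of C57BL/6J mice given quercetin or its vehicle. The labels give a quercetin dose of 0.125 mg/kg by gavage in 100 µL of phosphate-buffered saline with 10% PEG400. Per the labels, RNA was extracted with TRIzol, treated with a DNA removal kit and made into libraries with a NEBNext Ultra kit. The depot of the white fat and the age, sex and treatment time of the sequenced animals are not given in the sources used here; a start at 14 months of age is stated for the lifespan part of the work only.

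The deposited files hold 1 count per Ensembl gene for each of the 18 libraries, without normalisation. Per the submitters' processing notes, HISAT2, HTSeq and DESeq2 were used with the mouse build mm10, without versions. The annotation release and the strand setting of the count step are not given there. Each file held 53465 genes and 5 summary lines, of which the lines for reads without a feature and for ambiguous reads were used as quality measures only. A symbol was assigned to 53274 of the gene identifiers from the GENCODE mouse annotation of GRCm38, which also gave the coordinates printed in the report. Counts summed over genes ranged from 8436308 to 12311345 per library. Reads without a feature made up 2.53 to 9.11% and ambiguous reads 6.47 to 9.84%. No pair of replicates within a group of tissue and treatment was close enough to be a copy, since the lowest chi-square per degree of freedom of the 18 such pairs was 27.0.

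Samples were grouped by tissue and treatment into 6 groups of 3 libraries, from the labels alone. Each tissue was analysed by itself with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, normalised by TMM, fitted with glmQLFit and tested two-sided with the quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in the tissue, and the threshold was 0.05. The difference of the quercetin effect between tissues was tested as an interaction contrast in a fit of all 18 libraries. The p-values measure the spread between these libraries. The design had 3 libraries against 3, for which an exact permutation test of a single gene cannot give a p below 0.1.

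Gene lists were tested with camera of limma 3.58.1, with a preset correlation between genes of 0.01, adjusted over the lists tested in the tissue. The 34 lists hold 941 gene entries, of which 2 symbols had no match. They cover energy metabolism, fat and sterol synthesis, muscle, stress and turnover pathways, and markers of the cell types such samples could hold. Each list was also tested with a correlation estimated from the data and with fry, which asks whether the genes of a list move on balance one way. Members were counted as past the threshold over all genes and adjusted over the list alone. The groups, tests, lists, thresholds, alternatives and the rule for named genes were fixed before the data were examined, apart from the additions named as such.

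The rule for named genes took, in each tissue, up to 10 genes that rose and 10 that fell past the threshold, 4 members with the smallest p of each list past its threshold, and a panel of 4 genes. Since fewer than 10 genes passed in each tissue, it also took the 5 genes with the smallest unadjusted p, given as not passing. Members are printed for the 6 lists with the smallest camera p in each tissue, a limit set after the values were seen; the members of the other lists are given as counts. Some genes that the rule takes are left out of the text. Levels are CPM, counts scaled to a common library size by the cpm function of edgeR with TMM factors, with mean and SD over 3 libraries. CPM printed beside a fold change come from the fit of that tissue, and CPM set side by side across tissues come from the normalisation of all 18 libraries, so that the 2 differ for a gene. Log2 fold changes are quercetin minus vehicle, with a standard error from the fit, and intervals are 95% and unadjusted.

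The calculations were tested on simulated data with the dispersions and library sizes of each tissue, in which 100 genes were given a 4-fold and 100 a 16-fold change. In muscle, edgeR recovered 43% of the 4-fold and 86% of the 16-fold changes with 13 false calls. In white fat it recovered 2% and 36% with 3 false calls, and in brown fat 13% and 77% with 3 false calls. DESeq2 1.42.0 recovered 80% and 89%, 27% and 86%, and 51% and 89% in the same order, with 49, 75 and 40 false calls. A list shifted by 0.8 on the log2 scale was called with the preset correlation in all 3 tissues and with the estimated one in muscle and brown fat, not in white fat. Fry called it in all 3 tissues. Of the lists that were not shifted, the preset correlation called 1 and fry 2 in brown fat, and no other was called. The simulated genes varied independently of each other. These counts therefore could not show how often the preset correlation makes false calls on correlated genes. In the data, the median estimated correlation of the lists called with the preset was 0.30 in muscle, 0.64 in white fat and 0.50 in brown fat.

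The alternatives fixed in advance were DESeq2 size factors or library size in place of TMM, no filter on low counts, DESeq2 and limma voom as tools, the replicate number as a block, the flow cell as a covariate or the main flow cell alone, removal of mitochondrially encoded and haemoglobin genes, all 18 libraries or the 12 of a pair of tissues in the fit, an adjusted threshold of 0.1 for shared calls, and leaving out each library in turn. Added after the data were seen were the adipocyte, B cell or fast muscle list mean as a covariate for muscle, white fat and brown fat in that order, limma voom with library weights, fits without vehicle 1 and quercetin 2 in muscle or without vehicle 1 and quercetin 3 in brown fat, and list tests on the 4 white fat libraries of the main flow cell. For the differences between tissues, the libraries with the same arm and number were left out together in all 3 tissues. No library was left out of the main comparisons.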

Results

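RNA sequencing counts were collected from skeletal muscle, white fat and brown fat of C57BL/6J mice on long-term low-dose quercetin, a plant flavonol, or on its PEG400 vehicle. Each of the 6 groups of tissue and treatment held 3 libraries, numbered 1 to 3, which made 18 in all. Counts summed over genes ranged from 8997823 to 12311345 per library in muscle, from 8612506 to 10283073 in white fat and from 8436308 to 11323696 in brown fat. Between 18928 and 22458 genes had a count in a library. Pearson's r of log2 CPM across genes between replicates was 0.895 to 0.965 in muscle, 0.677 to 0.947 in white fat and 0.844 to 0.974 in brown fat; genes are not independent replicates. The libraries came from flow cell H7H2WDSXX, except muscle quercetin 3, white fat vehicle 1 and white fat quercetin 2, which came from flow cell H7GKJDSXX. The titles number the animals in each arm without saying that a number pairs a quercetin with a vehicle animal.

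Muscle and brown fat markers were highest in the libraries labelled as those tissues. Acta1, the skeletal muscle actin, averaged 21082 ± 10153 CPM (SD, n = 3) in vehicle muscle, 97.8 ± 139 in vehicle white fat and 647 ± 733 in vehicle brown fat. Ucp1, the uncoupling protein of brown adipocytes, averaged 4148 ± 388 CPM in vehicle brown fat, 6.23 ± 10.2 in vehicle white fat and 0.461 ± 0.207 in vehicle muscle. Several libraries also held transcripts of other tissues. Brown fat quercetin 3 had 9149 CPM of Acta1 and 894 CPM of Ucp1, where the other 5 brown fat libraries had 1.32 to 1469 CPM of Acta1 and 3735 to 4745 CPM of Ucp1. Muscle quercetin 2 had 279.7 CPM of Ucp1 against at most 0.699 in the other 5 muscle libraries. White fat vehicle 2 had 17.9 CPM of Adipoq, the adipocyte hormone adiponectin, against 325 to 1100 CPM in the other white fat libraries. Muscle vehicle 3 held fat transcripts, with 471 CPM of Adipoq and 318 CPM of the adipocyte marker Plin1. The other 5 muscle libraries had 3.49 to 187 and 2.29 to 147 CPM of these. Ms4a1, a B cell marker, lay between 71.6 and 361 CPM in white fat vehicle 2 and 3 and quercetin 1 and 3, and at 0 and 0.438 CPM in vehicle 1 and quercetin 2.

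**Figure D1:**
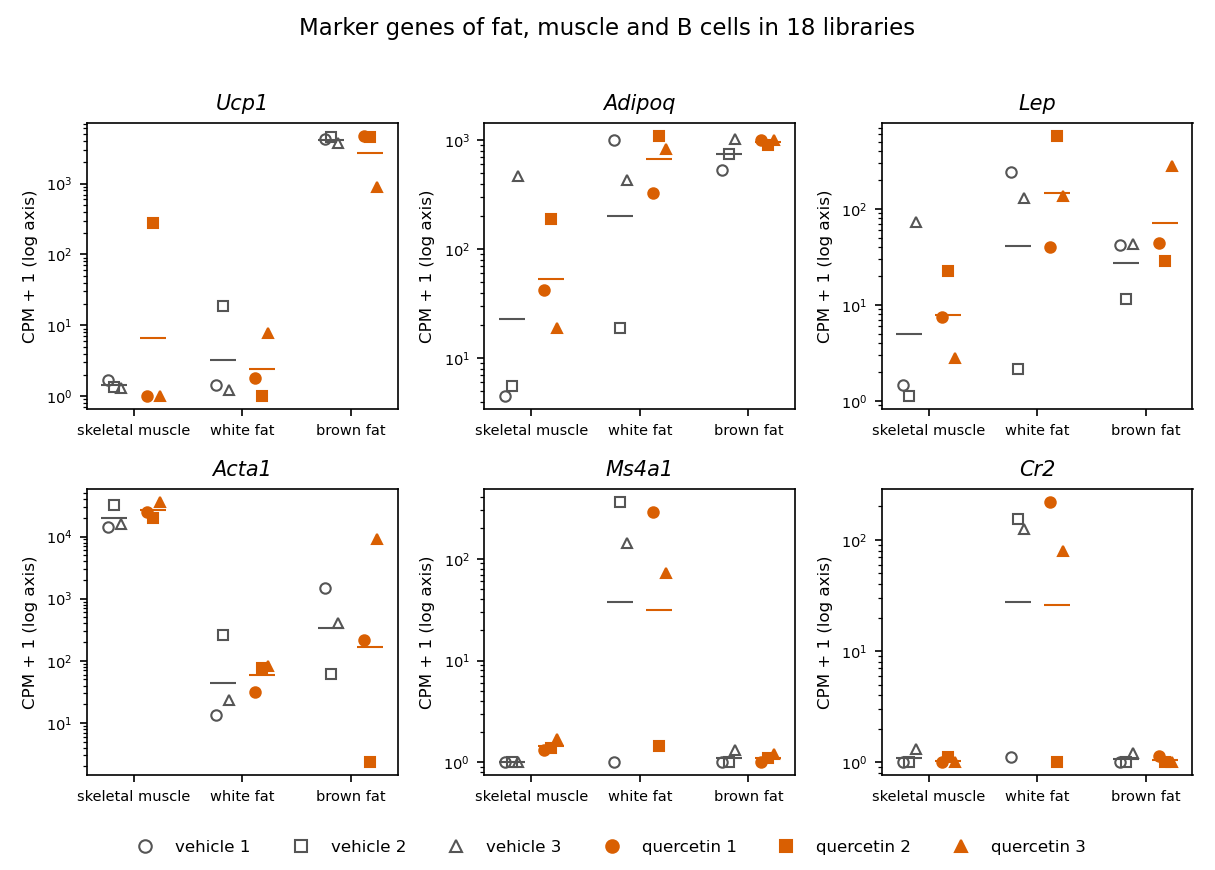
CPM + 1 on a log axis of 6 marker genes in each of the 18 libraries, by tissue, with vehicle in open grey and quercetin in filled orange symbols and a line at the geometric mean of CPM + 1 of each group. Ms4a1 and Cr2, both B cell genes, separate 4 white fat libraries from the other 14, and brown fat quercetin 3 stands apart with 9149 CPM of Acta1 and 894 CPM of Ucp1.

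In skeletal muscle, the question was which transcripts differed after low-dose quercetin. Genes of the muscle atrophy and denervation list were lower with quercetin: 23 of its 26 members had a lower and 3 a higher estimate, with a median log2 fold change of -0.79. The camera call of this list was lost with an estimated correlation (adjusted p = 0.737). Over all genes 0 members passed, and the median was -0.44 without vehicle 1. Mt1, a metallothionein, averaged 2175 ± 1840 CPM with vehicle and 293 ± 169 with quercetin (SD, n = 3), with 4225 CPM in vehicle 1 and 664 and 1637 in the other vehicle libraries. Gadd45a, a growth arrest gene induced by denervation, averaged 168 ± 128 and 43.3 ± 7.78 CPM. Foxo1, a transcription factor that drives atrophy genes, averaged 122 ± 64.0 and 48.3 ± 4.31 CPM. Genes of MHC class II antigen presentation were higher in 7 of 7 members, with a median of 1.30 and an adjusted p of 0.737 with an estimated correlation. H2-Aa averaged 24.1 ± 18.8 CPM with vehicle and 59.4 ± 17.0 with quercetin.

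No single muscle gene passed the threshold. The 5 genes with the smallest unadjusted p were all lower with quercetin and separated in all 6 libraries. Cldn5, a tight junction protein of endothelial cells (ENSMUSG00000041378, chromosome 16, 18776847 to 18778262, build GRCm38), averaged 162 ± 116 CPM with vehicle and 29.3 ± 7.65 with quercetin, a log2 fold change of -2.46 ± 0.52 (SE). Cldn15, another claudin, was at 21.5 ± 6.85 and 6.92 ± 1.62 CPM, Prune2 at 25.3 ± 15.4 and 6.52 ± 0.920 CPM, and Prrt3 at 2.12 ± 0.190 and 0.164 ± 0.157 CPM. Of the fixed panel, Ppargc1a, a regulator of mitochondrial genes, had a log2 fold change of 0.27 (95% interval -1.05 to 1.59), and Myh4, the fast IIb myosin, -0.14 (-1.18 to 0.91). Myh7, the slow myosin, had -1.85 (-5.37 to 1.68), and Cdkn1a, the cell cycle inhibitor p21, -2.04 (-3.75 to -0.33). These values did not pass after adjustment, with adjusted p = 0.910 in edgeR for Myh7 and Cdkn1a. Single libraries carried them: Cdkn1a was at 1359.6 CPM in vehicle 1 and 98.6 to 242 in the other 5, and Myh7 at 30.5 CPM in vehicle 2 and 0.311 to 8.53 in the others. Without vehicle 1 the values were -0.67 for Cdkn1a, -0.17 for Ppargc1a and 0.20 for Myh4. Without vehicle 2, Myh7 was at 0.90 and Ppargc1a at 1.12, and without quercetin 3, Myh7 was at -4.51.

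Other muscle lists are given by their members. Cytosolic ribosomal protein genes were lower in 64 of 65 members (median -0.40, adjusted p = 0.792 with an estimated correlation), among them Rpl30 at 92.4 ± 42.1 and 48.5 ± 12.7 CPM, Rps27 at 379 ± 278 and 137 ± 100 CPM, Rplp2 at -0.80 ± 0.45 and Rpl3 at -0.64 ± 0.37 (log2 ± SE). Macrophage markers were higher in 23 of 28 (median 0.43, adjusted p = 0.738 with an estimated correlation), with Csf1r, the receptor of macrophage colony-stimulating factor, at 15.8 ± 11.3 and 39.1 ± 11.1 CPM, Adgre1 at 1.68 ± 0.91, Cd209f at 1.5 ± 0.82 and Aif1 at 1.09 ± 0.60 (log2 ± SE). Fibroblast markers were higher in 17 of 20 (median 0.55, adjusted p = 0.738 with an estimated correlation), with Abca8a at 45.4 ± 26.9 and 103 ± 11 CPM, Smoc2 at 0.76 ± 0.38 and Dcn, the matrix proteoglycan decorin, at 0.57 ± 0.40 (log2 ± SE). Has1, also named by the rule, was at 20.97 CPM in quercetin 1, at 0.730 and 1.07 in the other quercetin libraries and at 0.311 to 2.48 with vehicle. Autophagy and lysosome genes were lower in 33 of 41 (median -0.30, adjusted p = 0.738 with an estimated correlation), with Ctsl, a lysosomal protease, at 517 ± 572 and 137 ± 8.36 CPM, Bnip3, a mitophagy receptor, at 303 ± 332 and 86.6 ± 13.4 CPM, Atp6v1h at -1.73 ± 0.62 and Gabarapl1 at -1.25 ± 0.49 (log2 ± SE). The remaining MHC class II genes named by the rule were H2-DMb1 at 1.82 ± 0.73, H2-DMa at 1.67 ± 0.75 and H2-Ab1 at 1.38 ± 0.79 (log2 ± SE). Lists of extracellular matrix genes (32 of 44 higher, median 0.25), peripheral nerve markers (13 of 16, 0.41), fast-twitch muscle genes (22 of 28, 0.31), T cell markers (4 of 4, 0.76), B and plasma cell markers (4 of 5, 1.58) and thermogenic genes (16 of 25, 0.45) were also called higher by camera. With an estimated correlation these calls were lost, with adjusted p between 0.737 and 0.792. Heat shock and endoplasmic reticulum stress genes (27 of 34 lower, median -0.31), antioxidant genes (26 of 35, -0.26), endothelial markers (13 of 21, -0.20) and cell cycle inhibitors and p53 targets (13 of 21, -0.28) were called lower. They too were lost with an estimated correlation, at adjusted p between 0.737 and 0.738.

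Vehicle 1 stood apart from the other muscle libraries in the same gene groups. Trim63 and Fbxo32, which encode the muscle ubiquitin ligases MuRF1 and atrogin-1, were at 8480 and 5923 CPM in vehicle 1, against 421 to 861 and 273 to 412 CPM in the other 5 muscle libraries. H2-Aa was at 3.22 CPM in vehicle 1 and at 29.7 to 72.5 CPM in the others, and Csf1r at 3.73 against 17.4 to 51.3 CPM. Ctsl was at 1178 CPM in vehicle 1 and at 130 to 188 CPM in the others. Many of the named log2 fold changes shrank without this library. They became -1.12 for Gadd45a, -0.81 for Foxo1, 0.78 for H2-Aa and 0.86 for H2-Ab1. The ribosomal genes Rpl30, Rps27, Rplp2 and Rpl3 became -0.57, -0.74, -0.29 and -0.30, and the autophagy genes Ctsl, Bnip3, Atp6v1h and Gabarapl1 -0.44, -0.35, -0.61 and -0.57. Csf1r, Cd209f and Aif1 became 0.85, 0.99 and 0.68, and Smoc2 and Dcn 0.50 and 0.32. Muscle quercetin 2 held brown fat transcripts of the thermogenic list, with 199.8 CPM of Cidea against at most 18.9 in the other muscle libraries.

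**Figure D2:**
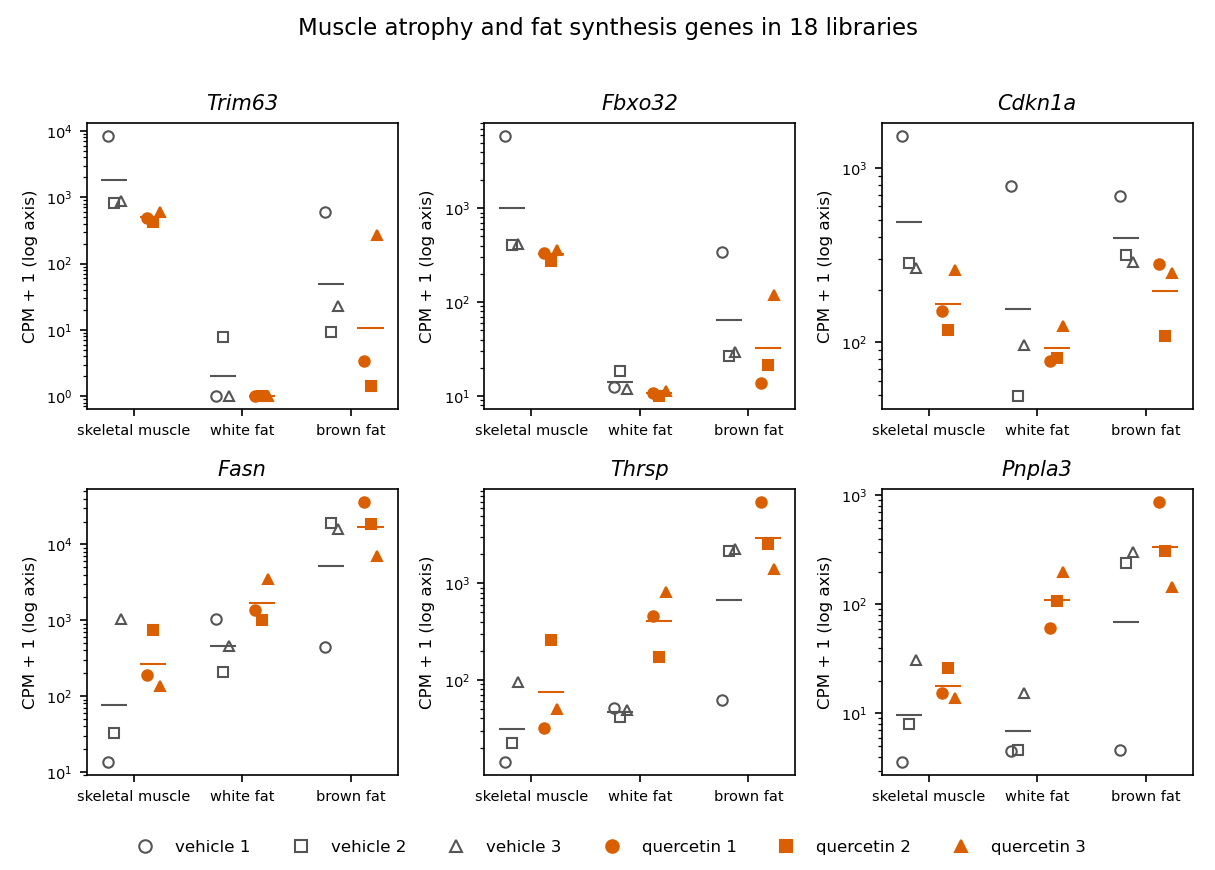
CPM + 1 on a log axis of 3 muscle catabolic genes and 3 fat synthesis genes in each of the 18 libraries, by tissue, with vehicle in open grey and quercetin in filled orange symbols and a line at the geometric mean of CPM + 1 of each group. Trim63 and Fbxo32 reach 8480 and 5923 CPM in muscle vehicle 1, and Fasn is at 447 CPM in brown fat vehicle 1.

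By edgeR, 0 of 13562 muscle genes passed (smallest adjusted p = 0.910), and DESeq2, limma voom and limma voom with library weights also gave 0. Without the filter on low counts, 32 of 26302 genes passed in edgeR, 20 higher and 12 lower. Of the 20 higher genes, 15 had over 90% of their muscle CPM in quercetin 2, among them Ucp1, Ceacam10 and genes of the seminal vesicle secretion such as Svs2, Svs4 and Svs5. The other 5 were antibody genes such as Ighg1 and Igkv3-2. The lower ones included Cldn5 and Mt1, and 2 of the 12 had over 90% of their muscle CPM in vehicle 1. At an unadjusted p under 0.05, 406 genes were found by edgeR, 132 higher and 274 lower, where 678 were expected by chance. Such genes numbered 1728 without vehicle 3, which held fat transcripts, and 143 to 824 without 1 of the other libraries. No gene passed the adjusted threshold in those fits. The libraries of both arms did not overlap for 9.25% of genes, against 10% by chance. Camera called 16 of 34 lists, 9 higher and 7 lower, with an adjusted p of 5.73e-09 for atrophy and denervation, 1.93e-07 for MHC class II, 2.15e-06 for ribosomal proteins, 7.50e-06 for macrophages, 1.25e-05 for fibroblasts and 0.000423 for autophagy. With an estimated correlation no list was called. Over all genes 0 members of any list passed, and adjusted over the list alone 5 did, all lower, among them Mt1 and Gadd45a of the atrophy list, Cldn5 of the endothelial list and Cldn15 of the mesothelial list. The 18 lists that camera did not call had adjusted p between 0.0533 and 0.888: sterol synthesis, glycolysis, circadian, fat synthesis, fatty acid oxidation, immediate early, slow muscle, red blood cell, neutrophil, interferon, mesothelial, adipocyte, respiratory chain, inflammatory, aryl hydrocarbon receptor, mitochondrially encoded, epithelial and cell cycle genes. Without vehicle 1, 9 of the 16 calls ended, those of ribosomal, macrophage, fibroblast, autophagy, matrix, nerve, p53, T cell and thermogenic genes, while the atrophy median became -0.44 and that of MHC class II 0.82, both still called. The matrix median turned to -0.14 without it. Leaving out another library ended 1 to 5 calls: without quercetin 2 that of the thermogenic list, with a median of -0.14, without vehicle 2 that of heat shock genes, without quercetin 1 those of matrix and antioxidant genes, without vehicle 3 those of endothelial, fast muscle, antioxidant and p53 genes, and without quercetin 3, the library of flow cell H7GKJDSXX, those of B cell, endothelial, fast muscle, p53 and heat shock genes, so that 11 of 16 were called within flow cell H7H2WDSXX.

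In white fat, the same question was asked. Genes of fatty acid and triglyceride synthesis were higher with quercetin, in 18 of 24 members, with a median log2 fold change of 0.48. The camera call of this list was lost with an estimated correlation (adjusted p = 0.596). The mean log2 CPM of adipocyte markers was 3.90 in vehicle 2, 7.25 and 9.34 in the other vehicle libraries and 7.06 to 9.30 with quercetin. Thrsp, a regulator of lipid synthesis (ENSMUSG00000035686, chromosome 7, 97412938 to 97417730), averaged 61.9 ± 9.78 CPM with vehicle and 636 ± 428 with quercetin (SD, n = 3), a log2 fold change of 3.36 ± 0.63 (SE). Pnpla3, a lipid droplet protein induced by feeding (ENSMUSG00000041653, chromosome 15, 84167837 to 84187236), averaged 9.72 ± 8.63 and 160 ± 91.7 CPM, or 4.04 ± 0.82. Acss2 and Acly, which make acetyl-CoA, averaged 26.6 ± 5.81 and 87.7 ± 39.7 CPM and 173 ± 12.6 and 373 ± 101 CPM. Genes of sterol synthesis were higher in 17 of 22 members (median 0.43, adjusted p = 0.596 with an estimated correlation), and Sc5d, a late enzyme of that pathway, averaged 26.6 ± 3.34 and 60.9 ± 18.5 CPM.

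No single white fat gene passed the threshold in edgeR. The 5 genes with the smallest unadjusted p were all higher with quercetin in all 3 against all 3 libraries. Beside Thrsp they were Angptl8, a secreted inhibitor of lipoprotein lipase activity (ENSMUSG00000047822, chromosome 9, 21835510 to 21837347), at 1.16 ± 0.310 and 9.23 ± 3.66 CPM, and Ptger3, a prostaglandin E receptor, at 2.37 ± 0.794 and 14.5 ± 5.08 CPM. Slc25a35, a mitochondrial carrier, was at 7.17 ± 0.763 and 21.5 ± 1.68 CPM, and A830018L16Rik at 0.375 ± 0.113 and 4.78 ± 2.02 CPM. Of the panel, Lep, the hormone leptin, had a log2 fold change of 0.99 (95% interval -2.97 to 4.96), Adipoq 0.60 (-2.43 to 3.62), Ucp1 -1.24 (-6.23 to 3.75) and Adgre1, a macrophage marker, 0.71 (-1.67 to 3.09). Single libraries carried these values too: Lep and Adgre1 were highest in quercetin 2, at 784.5 and 93.0 CPM, and turned to -0.56 and -0.71 without it. Ucp1 was at 22.8 CPM in vehicle 2 and 0 to 9.01 in the others and turned to 2.88 without vehicle 2, and Adipoq was then at 0.029. Without vehicle 1, Adipoq was at 1.73 and Lep at 1.97.

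Fast-twitch muscle genes were lower in 16 of 16 members measured in white fat (median -2.12, adjusted p = 0.742 with an estimated correlation): Tnnt3, a fast troponin, was at 356 CPM in vehicle 2 and 0.757 to 19.7 CPM in the other 5 libraries, Myh4 at 141 CPM in vehicle 2 and 0 to 10.2 CPM in the others, Pgam2 at 38.1 against 1.98 to 6.96 CPM and Casq1 at 10.0 against 0.192 to 2.42 CPM. Immediate early genes were lower in 23 of 26 (median -0.85, adjusted p = 0.913 with an estimated correlation), with Zfp36 at 1386 CPM in vehicle 1 and 96.7 to 242 CPM in the others, Atf3 at 64.6 against 2.40 to 14.9 CPM, Klf6 at 478 against 98.8 to 141 CPM and Btg2 at 801 against 51.1 to 234 CPM. Without vehicle 1 their log2 fold changes were -0.14, -0.46, -0.15 and -0.37. Adipocyte markers were higher in 12 and lower in 12 of 24 (median 0.11, adjusted p = 0.913 with an estimated correlation), with Adrb3, the beta-3 adrenergic receptor, at 39.4 ± 48.6 and 253 ± 189 CPM, Nnat at 3.13 ± 1.63, Lgals12 at 1.99 ± 1.17 and Sncg at 1.79 ± 1.2 (log2 ± SE). Without quercetin 2, Nnat was at 1.53 and Sncg at 0.64. Interferon-stimulated genes were higher in 27 of 32 (median 0.28, adjusted p = 0.913 with an estimated correlation), with Oas2 at 1.29 ± 0.79, Mx1 at 0.91 ± 1.06 and Xaf1 at 0.45 ± 0.57, while Rsad2 was at -0.58 ± 0.62 (log2 ± SE). Without vehicle 1 they were at 0.79, 0.34, 0.010 and -0.30. The other sterol synthesis genes named by the rule were Nsdhl at 0.97 ± 0.42, Msmo1 at 0.66 ± 0.39 and Tm7sf2 at 0.63 ± 0.39 (log2 ± SE). Nsdhl was at 0.64 without quercetin 3 and Msmo1 at 0.43 without vehicle 1. Also called higher were respiratory chain genes (56 of 69, median 0.23), fibroblast markers (18 of 18, 0.61), thermogenic genes (13 of 24, 0.12), aryl hydrocarbon receptor targets (9 of 17, 0.11) and neutrophil markers (10 of 11, 1.02). These calls were lost with an estimated correlation (adjusted p = 0.913 for each). Called lower were cell cycle genes (29 of 30, median -1.10), ribosomal protein genes (58 of 66, -0.15), endothelial markers (21 of 22, -0.84), red blood cell genes (7 of 8, -2.13) and the atrophy list (11 of 15, -0.28). They were lost with an estimated correlation, at adjusted p between 0.742 and 0.954.

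By edgeR, 0 of 14919 white fat genes passed (smallest adjusted p = 0.9998). Limma voom, with or without library weights, also gave 0, and DESeq2 gave 7, with Slc25a35, Angptl8, Thrsp, Ptger3, Pnpla3 and A830018L16Rik higher and Gm13123 lower. On simulated data of this tissue, DESeq2 made 75 false calls. It also found 27 of 100 genes changed 4-fold and 86 of 100 changed 16-fold. At an unadjusted p under 0.05, edgeR found 122 genes, 73 higher and 49 lower, where 746 were expected by chance, and the arms did not overlap for 4.60% of genes, against 10% by chance. Camera called 16 of 34 lists, 9 higher and 7 lower, with an adjusted p of 3.64e-13 for fat synthesis, 7.36e-11 for fast muscle, 1.85e-07 for immediate early genes, 1.96e-05 for adipocyte markers, 5.28e-05 for interferon genes and 9.09e-05 for sterol synthesis. With an estimated correlation no list was called. Over all genes 0 list members passed, and adjusted over the list alone 3 did, all higher: Thrsp, Pnpla3 and Acss2 of fat synthesis. The 18 lists not called had adjusted p between 0.0563 and 0.927: slow muscle, matrix, heat shock, circadian, B cell, mitochondrially encoded, autophagy, fatty acid oxidation, T cell, mesothelial, MHC class II, inflammatory, nerve, glycolysis, antioxidant, epithelial, macrophage and p53 genes.

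Fat and sterol synthesis were the white fat lists called in each of the 6 fits without 1 library, with medians of 0.19 to 1.87 and 0.23 to 0.45. Both lists lost their call with an estimated correlation and with fry on the full set. Within flow cell H7H2WDSXX, 2 libraries against 2, their medians were 1.89 and 0.25 and both were called, and 8 of the 16 lists were called in the direction of the full set. In that flow cell, interferon genes had a median of -0.28, neutrophil markers -0.48, fibroblast markers -0.19, endothelial markers 0.17 and immediate early genes 0.29. Flow cell H7GKJDSXX held 1 white fat library of each arm, too few for a value. Without vehicle 2 the calls of adipocyte, aryl hydrocarbon receptor, fast muscle, fibroblast, neutrophil, respiratory chain and ribosomal genes ended, and the cell cycle median turned to 0.16 with an adjusted p of 0.0456 in camera. Without vehicle 1 the calls of atrophy, red blood cell and immediate early genes ended and the medians of interferon and endothelial genes turned to -0.26 and 0.57, both called. Without quercetin 2 the calls of adipocyte, aryl hydrocarbon receptor, fibroblast, cell cycle and ribosomal genes ended and the neutrophil median turned to -1.06, which was called. Without quercetin 1 the calls of atrophy, endothelial and red blood cell genes ended, without quercetin 3 those of aryl hydrocarbon receptor, atrophy, red blood cell, respiratory chain and thermogenic genes, and without vehicle 3 those of atrophy, neutrophil, respiratory chain and thermogenic genes.

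In brown fat, the thermogenic genes were the tissue's own program. Ucp1 (ENSMUSG00000031710, chromosome 8, 83290352 to 83298452) averaged 3631 ± 375 CPM with vehicle and 2910 ± 1800 with quercetin (SD, n = 3), a log2 fold change of -0.32 (95% interval -1.73 to 1.09). Cidea, a lipid droplet protein of brown adipocytes, had 0.00 (-1.38 to 1.37), Ppargc1a -1.26 (-3.11 to 0.59) and Dio2, which activates thyroid hormone, -1.22 (-4.0 to 1.55). Without vehicle 2, Ppargc1a was at -0.45 and Dio2 at -0.25, and without quercetin 3, Ucp1 was at 0.13 and Cidea at 0.43. Other fits moved them the other way. Without quercetin 2, Ppargc1a was at -2.14 and Dio2 at -3.71, and without quercetin 1, Ucp1 was at -0.63 and Cidea at -0.44. The thermogenic list was lower in 25 of 30 members, with a median of -0.30, and its camera call was lost with an estimated correlation (adjusted p = 0.774). Without quercetin 3, which also held muscle transcripts, the median was 0.026. Ucp1 was at 832 CPM there and at 3980 and 3917 CPM in the other quercetin libraries. Elovl3, a fatty acid elongase of brown fat, was at 526 ± 328 and 163 ± 117 CPM. Slc25a34, a mitochondrial carrier (ENSMUSG00000040740, chromosome 4, 141618824 to 141623821), averaged 98.9 ± 37.0 and 14.6 ± 4.91 CPM, and Tead1, a transcription factor of the Hippo pathway (ENSMUSG00000055320, chromosome 7, 112679318 to 112906807), 159 ± 16.1 and 71.0 ± 9.99 CPM.

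The 5 genes with the smallest unadjusted p had their arms apart in all 6 libraries, and none passed the threshold in edgeR. Slc25a34 and Tead1 had log2 fold changes of -2.75 ± 0.40 and -1.16 ± 0.26 (SE), and 3930402G23Rik was at 8.62 ± 2.91 and 2.16 ± 0.722 CPM. Igkv14-126, an antibody light chain gene, was at 1.13 ± 0.115 and 6.26 ± 3.24 CPM, and Alb, the serum albumin gene of liver, at 0.187 ± 0.192 and 23.8 ± 32.5 CPM, with 61.2 CPM in quercetin 1 and 3.43 and 6.61 in the others.

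Interferon-stimulated genes were higher in 32 of 32 members (median 2.47, adjusted p = 0.774 with an estimated correlation), and quercetin 3 held most of their transcripts: Rsad2 was at 518 CPM there and 15.5 to 27.3 in the other 5 libraries, Cmpk2 at 512 against 1.86 to 26.2 CPM, Usp18 at 182 against 0.710 to 10.9 CPM and Mx1 at 82.0 against 0.264 to 2.92 CPM. Respiratory chain genes were higher in 67 of 69 (median 0.32, adjusted p = 0.774 with an estimated correlation), with Ndufa12 of complex I at 121 ± 50.8 and 320 ± 57.3 CPM and Ndufb7 at 0.67 ± 0.40 (log2 ± SE). For 2 others quercetin 3 stood apart. Atp5g1 was at 363 CPM there against 4.83 to 31.5 in the other 5 libraries, and Atp5j at 439.7 against 109.9 to 167 CPM. Sterol synthesis genes were higher in 17 of 22 (median 0.53, adjusted p = 0.774 with an estimated correlation), with Sc5d at 38.7 ± 15.9 and 83.9 ± 29.5 CPM, Mvd at 1.60 ± 0.55, Mvk at 0.75 ± 0.37 and Dhcr7 at 1.27 ± 0.64 (log2 ± SE). Dhcr7 was at 44.5 CPM in quercetin 1 and 4.79 to 14.4 in the others, and without quercetin 1 Mvd, Mvk and Dhcr7 were at 0.98, 0.37 and 0.35. Fat synthesis genes were higher in 21 of 24 (median 0.63, adjusted p = 0.774 with an estimated correlation). Srebf1, a transcription factor of that pathway, was at 187 ± 37.8 and 304 ± 49.3 CPM. Scd2 was at 1.46 ± 0.97, Tkfc at 0.63 ± 0.47 and Me1 at 0.72 ± 0.60 (log2 ± SE). Without quercetin 1, where Scd2 was at 747 CPM against 17.7 to 243 in the others, these 3 were at 0.35, 0.27 and 0.39, and without vehicle 1 at 0.93, 0.31 and 0.31. Fasn, fatty acid synthase, was at 447 CPM in vehicle 1 and 7051 to 36395 CPM in the other 5 libraries. Ribosomal protein genes were higher in 63 of 65 (median 0.34, adjusted p = 0.774 with an estimated correlation), with Rps19 at 632 CPM in quercetin 3 and 295 to 392 in the other 5 libraries, Rpl29 at 317 against 91.7 to 145 CPM and Rps24 at 829 against 291 to 394 CPM. The other thermogenic genes named by the rule were Bmp8b at -1.75 ± 1.11 and Fabp3 at -0.64 ± 0.47 (log2 ± SE). Without vehicle 1, Bmp8b was at -1.07, Fabp3 at -0.019 and, of the other named genes, Elovl3 at -1.07 and Ndufb7 at 0.42. Also called were MHC class II (7 of 7 higher, median 0.55), nerve (11 of 13, 1.01), fibroblast (16 of 19, 0.32) and T cell genes (2 of 2, 1.66), and lower fatty acid oxidation (22 of 31, -0.15) and cell cycle genes (9 of 13, -0.54). These calls too were lost with an estimated correlation (adjusted p = 0.774). Of them only that of cell cycle genes was made without quercetin 3.

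By edgeR, 0 of 13274 brown fat genes passed (smallest adjusted p = 0.977). Limma voom, with or without library weights, also gave 0, and DESeq2 gave 2, Slc25a34 and Alb. On simulated data of this tissue, DESeq2 made 40 false calls. It also found 51 of 100 genes changed 4-fold and 89 of 100 changed 16-fold. At an unadjusted p under 0.05, edgeR found 241 genes, 108 higher and 133 lower, where 664 were expected by chance, and the arms did not overlap for 6.23% of genes, against 10% by chance. Camera called 12 of 33 lists, 9 higher and 3 lower, with an adjusted p of 4.09e-09 for interferon genes, 6.31e-05 for the respiratory chain, 0.000250 for thermogenic genes, 0.000843 for sterol synthesis, 0.000994 for fat synthesis and 0.00212 for ribosomal proteins. With an estimated correlation no list was called. Over all genes and adjusted over the list alone, 0 members of any list passed by edgeR. The 21 lists not called had adjusted p between 0.0623 and 0.944: slow and fast muscle, macrophage, autophagy, immediate early, endothelial, atrophy, inflammatory, neutrophil, aryl hydrocarbon receptor, circadian, glycolysis, red blood cell, adipocyte, heat shock, antioxidant, mesothelial, B cell, mitochondrially encoded, p53 and matrix genes. The list of epithelial markers had no gene above the count filter.

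No brown fat list was called in each of the 6 fits without 1 library. Without quercetin 3 the medians turned to -0.63 for interferon genes and -0.19 for ribosomal proteins, both called, and to 0.026 for thermogenic genes and 0.22 for fatty acid oxidation, not called; the calls of MHC class II, nerve, fibroblast and T cell genes ended, and 1 gene, Gm12033, passed. Without vehicle 1 the calls of the respiratory chain, sterol and fat synthesis, MHC class II, cell cycle and T cell genes ended, with medians of 0.09, 0.24 and 0.31 for the first 3. Without quercetin 1 those of the respiratory chain, sterol and fat synthesis and T cell genes ended. Without quercetin 2 those of fat synthesis, cell cycle and T cell genes ended, without vehicle 2 those of fibroblast, ribosomal and T cell genes, and without vehicle 3 those of cell cycle, ribosomal, nerve and T cell genes. All 6 brown fat libraries came from 1 flow cell.

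**Figure D3:**
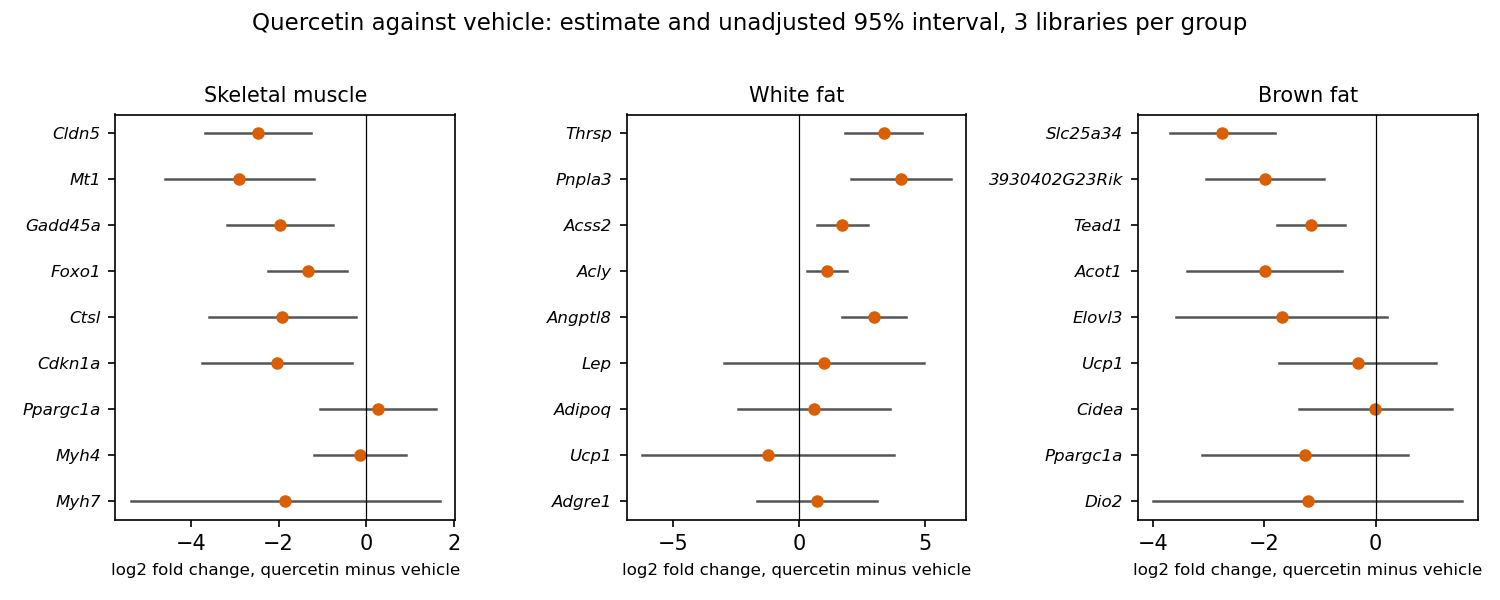
Log2 fold change, quercetin minus vehicle, of 9 genes in each tissue with its unadjusted 95% interval as a horizontal bar, from 3 libraries per group. In white fat Thrsp is at 3.36 and Pnpla3 at 4.04, in brown fat Ucp1 is at -0.32 with an interval of -1.73 to 1.09, and no gene passed after adjustment.

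Across the tissues, the question was whether the quercetin effect differed. The test of the difference by edgeR passed 0 of 16388 genes for brown against white fat, for brown fat against muscle and for white fat against muscle. This fit takes the 18 libraries as independent. With the animal number as a block 0 genes passed for each difference. At an unadjusted p under 0.05 there were 173, 223 and 231 genes in that order, where 819 were expected by chance. DESeq2 gave 13, 2 and 7 genes. The 13 included muscle genes such as Xirp2, Ckm, Actn3 and Tnnt3. Acta1, also a muscle gene, was at 9149 CPM in brown fat quercetin 3 and 258 CPM in white fat vehicle 2. The other libraries of each tissue had 1.32 to 1469 and 12.5 to 81.2 CPM. The 2 were the antibody genes Ighv5-15 and Igkv4-53, and the 7 included Ighv5-15, Igkv3-2 and the muscle genes Xirp2, Myf6 and Sln. On simulated data with changes in brown fat alone DESeq2 made 40, 30 and 13 false calls. For brown against white fat it also found 27 of 100 genes changed 4-fold and 78 of 100 changed 16-fold. For brown fat against muscle it found 27 and 77, and for white fat against muscle no change had been set. No gene passed the threshold in a pair of tissues, at an adjusted p of 0.05 or 0.1 in edgeR. In muscle and brown fat, 15 genes were lower in both at an unadjusted p under 0.05 in edgeR, Bnip3, Acot2, an acyl-CoA thioesterase, and Ednrb, an endothelin receptor, among them, where 2.48 were expected if the tissues were independent, and 0 were higher in both. Without the vehicle 1 libraries, 3 were lower and 5 higher in both, where 0.781 and 0.801 were expected, so the excess was not in 1 direction. In both fats, 3 genes were lower and 2 higher (0.386 and 0.554 expected), and without vehicle 1, 0 and 8 (0.612 and 1.53 expected). In white fat and muscle, 0 were lower and 1 higher (0.799 and 0.468 expected), and without vehicle 1, 1 and 4 (1.05 and 2.72 expected). These names were chosen after the values were seen. The tissues may come from the same animals, so these counts carry no p-value. The median, mean and camera direction of a list differed in sign in 20 of the 101 list tests, none of them called.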

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

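Chosen after the data were seen were the fits with a cell makeup covariate, with library weights, without 2 libraries that stand apart in muscle or brown fat, and the list tests on the main flow cell of white fat; the other alternatives were fixed in advance.

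The count of 0 genes in muscle held under the alternatives run except the fit without a filter on low counts, which gave 32. In white fat DESeq2 gave 7 genes, and in brown fat DESeq2 gave 2 and the fits without quercetin 3 and without vehicle 1 and quercetin 3 gave 1 each; the other alternatives gave 0. For the differences between tissues DESeq2 gave 13, 2 and 7 genes (brown against white fat, brown fat against muscle, white fat against muscle) and the other alternatives gave 0. Leaving out each library in turn gave 0 to 0 genes in muscle and white fat and 0 to 1 in brown fat. For the differences, the libraries with the same arm and number were left out together in all 3 tissues, which gave 0 to 0. The overlap of calls was 0 at both thresholds. The cause of these changes was not tested.

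The counts of called lists became 0 in muscle, 0 in white fat and 0 in brown fat with an estimated correlation, and likewise 0, 0 and 0 with fry. Leaving out each library gave 12 to 20 lists in muscle, 14 to 23 in white fat and 8 to 15 in brown fat. With the replicate number as a block, 0 genes passed in each tissue, and 10 of the 16 white fat lists, 16 of the 16 muscle lists and 12 of the 12 brown fat lists were called in the direction of the fit without a block. The quercetin library closest to a vehicle library had the same number for 0 of 3 vehicle libraries in muscle, 0 in white fat and 1 in brown fat; the correlation of libraries with the same number across genes, after subtracting the mean of their arm, was -0.20 to -0.01 in muscle, -0.70 to 0.27 in white fat and -0.15 to 0.26 in brown fat, so the numbers were not read as pairs. Between tissues, vehicle libraries with the same number correlated at 0.13 to 0.26 for brown fat and muscle and at 0.18 to 0.30 for white fat and muscle, each best with its own number, and at 0.053 to 0.19 for both fats. Quercetin libraries with the same number correlated at -0.14 to 0.15, -0.029 to 0.11 and -0.13 to 0.019 in the same order. Of these, 2, 2 and 0 of 3 were best with their own number. For both fats, 2 of 3 vehicle libraries were. With the animal number as a block, 0 genes passed for the differences between tissues.

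Some medians (log2) of called lists changed sign when 1 library was left out; each range is the lowest to the highest of 6 fits. In muscle these were macrophage (-0.12 to 1.37), matrix (-0.14 to 1.08) and thermogenic genes (-0.14 to 0.78). In white fat they were neutrophil (-1.06 to 1.78), interferon (-0.26 to 0.71), endothelial (-1.35 to 0.57), red blood cell (-2.69 to 0.18), immediate early (-1.67 to 0.27), adipocyte (-0.48 to 2.03), aryl hydrocarbon receptor (-0.21 to 1.06), cell cycle (-1.68 to 0.16), ribosomal (-0.59 to 0.17), thermogenic (-0.24 to 0.67), atrophy (-0.44 to 0.00036) and fibroblast genes (-0.50 to 1.15). In brown fat they were thermogenic (-0.69 to 0.026), fatty acid oxidation (-0.44 to 0.22), interferon (-0.63 to 3.08), nerve (-0.37 to 1.37), cell cycle (-0.63 to 0.044), fibroblast (-0.0010 to 0.56) and ribosomal genes (-0.19 to 0.58).

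Without vehicle 1 and quercetin 2 in muscle, the thermogenic median was -0.23, and camera called the list lower (adjusted p = 0.00955). Without vehicle 1 and quercetin 3 in brown fat, the medians were 0.050 for thermogenic and 0.16 for fatty acid oxidation genes. They were -1.11 for interferon and -0.015 for ribosomal genes. Of these camera called interferon, lower (adjusted p = 4.88e-37). The libraries left out, vehicle 1 and quercetin 3, had the lowest and the highest interferon score, -2.46 and 3.87. In the 4 white fat libraries of flow cell H7H2WDSXX the medians were -0.28 for interferon, -0.48 for neutrophil and -0.19 for fibroblast genes. They were 0.17 for endothelial and 0.29 for immediate early genes. Of these camera called interferon, lower (adjusted p = 0.00378). These 3 fits had 2 libraries against 2 and used the preset correlation. An estimated correlation was not run on them. Without the filter on low counts the test direction of white fat neutrophil genes turned at a median of 1.04. The cause was not tested beyond the libraries left out.

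Of the named genes, fold changes turned sign in 12 of 1311 alternative values in muscle, 45 of 1275 in white fat and 26 of 918 in brown fat. Values that passed the threshold numbered 2, 6 and 2, and all kept the main direction. The spread between libraries limited the gene tests more in white fat, with a common biological coefficient of variation of 0.668, than in muscle (0.438) or brown fat (0.501); edgeR recovered 2% of simulated 4-fold changes there, against 43% and 13%.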

Other observations

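The tests of depth in the vehicle 1 libraries, of muscle mixed into brown fat, of reads spread over a flow cell and both tests on the thermogenic list were chosen after the result was seen, as were the genes named in the next paragraph; the lists for fasting and lymph node and the counts over other splits were fixed before their results.

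Some libraries held transcripts at far higher levels than most others of their tissue, those of other organs among them. Muscle quercetin 2 held genes of the seminal vesicle secretion at 12350 CPM for Svs5, 6918 for Svs2, 5770 for Svs4 and 1331 for Ceacam10, while each of these was at most 0.418 CPM in the other 17 libraries. Brown fat quercetin 3 held the interferon-induced genes Ifit3 at 1675 CPM and Cmpk2 at 549.8 CPM, where the other brown fat libraries held 1.5 to 56.2 and 2.10 to 29.9 CPM. Liver genes stood out in brown fat quercetin 1, with Alb at 73.0, Apoa1 at 30.3 and Apoa2 at 12.9 CPM, against at most 7.10, 2.63 and 1.30 CPM in the other brown fat libraries. Gm12033 was at 331 and 683 CPM in muscle vehicle 3 and quercetin 3, at 84.8 CPM in white fat quercetin 2 and at 544 and 261 CPM in brown fat quercetin 1 and 2, against at most 3.92 CPM in the other 13 libraries.

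Vehicle 1 had high muscle atrophy genes in muscle and low fat synthesis genes in brown fat. Low depth or poor reads stayed open in all 3 tissues: the share of reads without a feature was 4.90% in muscle (2.53 to 5.31% in the others), with the second highest total but the fewest genes detected (19046 against 19271 to 21408) and the lowest TMM factor (0.740); 9.11% in white fat, with the lowest total and the fewest genes (20318 against 21131 to 22458); and 5.86% in brown fat, against 2.91 to 4.13%, but with the most genes (20554 against 18928 to 20066) and a total inside the range of the others. The test of muscle mixed into the brown fat of vehicle 1 took fat synthesis and thermogenic genes to fall alike. The fat synthesis score minus the thermogenic score was -1.83 in vehicle 1, against -0.16 to 1.12 in the others (SD 0.63). In brown fat quercetin 3 these scores were -0.73 and -1.71, at a fast muscle score of 4.71 against 2.06 in vehicle 1. They did not fall alike there, so the test as set could not decide. Other values go further. With less muscle than quercetin 3, vehicle 1 had the lower fat synthesis score, -1.75. Its Ucp1 was at 4206 CPM, against 3735 to 4745 CPM in the brown fat libraries other than quercetin 3. These values argue against muscle as the cause of the low fat synthesis genes in brown fat vehicle 1. A list of 10 fasting and glucocorticoid genes, none in the other lists and all with counts in each library, had its highest score in vehicle 1 in 3 of 3 tissues, at 1.35, 1.70 and 0.85 against at most -0.04, -0.10 and 0.12 in muscle, white fat and brown fat, but vehicle 1 was the highest library for only 8, 7 and 5 of the 10 genes. A fasting or glucocorticoid state of the vehicle 1 animal may therefore be a candidate explanation, if the number 1 marks 1 animal across tissues. The design gave no biological explanation to test against it. In white fat, the fat synthesis score of vehicle 1 was not low. It was 0.49, against -1.56 and -0.74 in the other vehicle libraries and 0.037 to 1.12 with quercetin. Scd1 was highest there, at 18026 CPM, while Pnpla3 was lowest, at 3.49 CPM. Its adipocyte score was also the highest, 1.83. A low fat synthesis list was thus not shared by the vehicle 1 libraries of all 3 tissues.

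B cell genes were high in 4 white fat libraries and near 0 in vehicle 1 and quercetin 2, both from flow cell H7GKJDSXX. Reads spread from 1 library over the main flow cell were argued against, since the lowest summed Ms4a1 and Cr2 level of the 4 libraries was 271 times the highest of the 11 muscle and brown fat libraries there. Lymph node tissue in the 4 samples could be the source but stayed open, with 4 of 6 lymph node genes higher in each of the 4 than in both others, where 5 had been asked for in advance. Glycam1 and Fcer2a were at 14.6 to 48.6 and 48.2 to 280 CPM in the 4 and at 0 in both others, while Ccl19 was near 0 throughout and Madcam1 was highest in vehicle 1 at 9.49 CPM. The flow cell and the presence of B cells cannot be told apart in white fat, and no other biological explanation was tested.

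The thermogenic list was lower with quercetin in brown fat. Without quercetin 3 its median was 0.026 and the call ended (adjusted p = 0.598 in camera), and that library had a fast muscle score of 4.71 against at most 2.06 in the others. The call thus depended on that library. Its muscle content may contribute, but white fat in it was not tested. Lep was at 275 CPM in it, against 10.4 to 43.3 CPM in the other brown fat libraries. Adipoq was at 1000 CPM, inside their range of 531 to 1032 CPM. The same library also had the highest interferon score, 3.87 against at most 0.55 in the others. A fall in every quercetin animal was not seen: the score of quercetin 2, 0.60, lay above the vehicle median of 0.31, and by mean log2 CPM over all 18 libraries it was at 7.50 against 7.49 in the highest vehicle library. It was not excluded, since 0 of the 3 quercetin libraries had a score above the highest vehicle library and these gaps were smaller than the range of the vehicle libraries.

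For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real count of genes was 0 in each tissue and for each difference between tissues. Any split gives as many, so the 10 of 10 splits of a tissue and the 50 of 50 drawn splits for the differences say nothing about chance. The highest other count was 0 in each tissue, and 31, 0 and 0 for brown against white fat, brown fat against muscle and white fat against muscle. As many lists were called in 7 of the 10 splits in muscle (16 in the real split, 23 as the highest other), in 8 of 10 in white fat (16 and 23) and in 9 of 10 in brown fat (12 and 21). The 4 white fat splits that kept both libraries of flow cell H7GKJDSXX together called 22, 22, 23 and 23 lists, and within flow cell H7H2WDSXX 8 of the 16 real calls were made in the same direction. At an unadjusted p under 0.05, the split of white fat that set vehicle 1, quercetin 2 and quercetin 3 against the rest gave 3324 genes in edgeR, against 122 in the real split, which points to a structure of the samples other than treatment. The highest such counts were 1487 in muscle and 1182 in brown fat, against 406 and 241 in the real splits.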
